A study of Mus musculus with 19 samples.

How the data were processed

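Total RNA from mouse plantaris tendon had been sequenced in 19 libraries, and no reads were used here. Per the labels, 3 libraries came from Scx+ control mice without tamoxifen, and 16 from mice given tamoxifen: 4 each from Scx+ and Scx- mice after 7 days and after 14 days of a growth stimulus. The title of the study calls the Scx- mice mice with a targeted deletion of scleraxis. The alleles, the kind of growth stimulus, the strain and the sex are not given in the labels, and the replicates are not stated to be separate animals, so every p measures the spread between samples. The submitters' notes name FastQC, STAR, DESeq2 and the genome build mm10, with no version and no statement of what each was used for.

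A pair of tables had been deposited. The first holds a scaled signal per gene and library, made by the authors from estimated read counts. These values are not whole: the low values of a library repeat in steps of its own, worth 0.592 to 1.99 units, but only 36.7% to 67.2% of them lie within 0.1 of a whole multiple of that step, where chance gives 20%. Whole reads could not be recovered, so the number of reads behind a value is unknown, and no counting interval or detection limit is given. Median ratios to the mean library were alike within each group. They were 0.838 to 0.857 in Scx- at day 14 and 0.994 to 1.09 in the other groups, with overlap between Scx- day 7 and Scx+ day 14. On the authors' scale at least Scx- day 14 thus stood apart. The second table, deposited by the authors for 15951 genes, holds a mean signal, a log2 fold change with its standard error, and an adjusted p-value for 8 comparisons; the adjustment method is not stated. It served only for the counts and the few gene values quoted as the authors'.

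The values were rescaled by medians of ratios over the 13703 genes above 0 in every library, with factors from 0.838 to 1.09. Of 24972 genes listed, 4029 were at 0 in every library. The 16625 genes with a rescaled value of at least 10 in at least 3 libraries were tested, on log2 of the value plus 2. All 5 groups were fitted in 1 model with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust variance moderation, and no covariate. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The test differs from the plan. The edgeR quasi-likelihood test planned before the data were examined, with DESeq2 and limma-voom as alternatives, was not run. It was planned for read counts, and the deposited values are scaled signals from which read counts could not be recovered. Fold changes are log2 with the standard error (SE) of the fit, and group values are means with their standard deviation (SD).

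The comparisons were Scx- against Scx+ at each day, the difference between these 2 effects, each stimulated group against the control, and day 14 against day 7 within each genotype. The 4 comparisons with the control share its 3 libraries, and there the stimulus cannot be parted from tamoxifen. For Scx- the genotype differs from the controls as well, since no unstimulated Scx- group was included. Also fixed at that stage were 35 gene lists from textbook knowledge (pathways and cell type markers), the named genes and most alternatives. Of these lists, 34 had at least 3 tested members; the list of mitochondrially encoded genes matched no listed gene and was not tested. Lists were tested with limma's camera, which compares the members with all other genes, at a preset correlation between genes of 0.01, and again with a correlation estimated from the data. The fry test, which asks whether the members move on balance in 1 direction and makes no comparison with other genes, was run as an alternative. Counts of list members are given from the adjustment over all tested genes and adjusted over the list alone. For Scx and for the mean log2 value of each list, exact two-sided permutation tests of 4 libraries against 4 were run, for which the smallest p is 0.0286. These permutation p-values were not adjusted over the lists.

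Genes were named by this rule: Scx, Mkx, Tnmd, Col1a1, Col1a2, Col3a1 and Fmod; for each comparison, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 ppm of the library total, a regular symbol and groups that do not overlap; and up to 4 members of each list that passed or had a member that passed, or 2 members as values where none did. Some were left out for length, and genes named outside the rule are marked as such. Positions are from GENCODE M21 on GRCm38 (mm10). How reads shared by close paralogues, such as Ifit3 and Ifit3b, Plac9a and Plac9b or the globin genes, were assigned is not stated, nor whether the libraries kept the strand.

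The alternatives were library totals or a trimmed mean in place of medians of ratios; no filter and a stricter filter (a mean of at least 1 ppm); a fit without robust moderation; the replicate number as a block; the mean of the skeletal muscle list as a covariate; a fit of only the groups compared; and each library left out in turn. Alternatives added after the data were seen were the deposited scale, pseudocounts of 0.5 and 8, sample quality weights, removal of the 2 Scx- day 14 libraries richest in muscle transcripts, the trimmed mean computed on deposited values, and an estimated correlation for the lists taken from the other day. The procedure was tested on simulated data, with known changes added to simulated libraries drawn from the fitted spread of each gene. Of genes changed by 1, 2, 3 and 4 log2 units, it recovered 50%, 78%, 90% and 88% at day 7 (2 false calls of 161) and 56%, 68%, 88% and 100% at day 14 (5 of 165). For the difference between the days it recovered 16%, 62%, 64% and 86% (5 of 120). The simulated noise was independent between genes and held no differences in muscle content between libraries. These rates may therefore not carry over to the data.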

Results

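Gene expression was measured by RNA sequencing of 19 libraries from mouse plantaris tendon, an ankle tendon of the hindlimb. Scleraxis (Scx), a transcription factor of the tendon lineage, was targeted in the Scx- mice. Unstimulated controls (n = 3 libraries) were set beside Scx+ and Scx- mice after 7 or 14 days of a growth stimulus (n = 4 in each of 4 groups). The deposited signal summed to 73.7 ± 5.98 M (mega) units per control library (SD, n = 3). At day 7 it summed to 46.5 ± 1.64 M in Scx+ and 43.0 ± 2.17 M in Scx-. At day 14 it was 45.1 ± 1.68 M in Scx+ and 42.0 ± 4.96 M in Scx- (SD, n = 4 each). Single libraries ranged from 36.6 to 79.8 M, and the number of reads behind these scaled values is unknown.

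Scx was nearly absent from every Scx- library. In Scx+ libraries its rescaled signal was 8044.2, 5608.8, 3293 and 2772.5 at day 7 and 5092.6, 3747.1, 5044.1 and 2095.7 at day 14. Scx- libraries held 17.2, 9, 8.9 and 5.7 at day 7 and 5.8, 2.5, 4.9 and 1.7 at day 14, and the controls 592.6, 442.5 and 318.7. The mean was 10.2 ± 4.91 against 4930 ± 2415 at day 7, a 483-fold difference (SD, n = 4 each; exact two-sided permutation p = 0.0286). At day 14 it was 3.73 ± 1.97 against 3995 ± 1411, a 1072-fold difference (SD, n = 4 each; exact permutation p = 0.0286, the smallest this design allows). Scx (chromosome 15, 76457452 to 76459458, 3 annotated exons, GRCm38) lies on the plus strand within Bop1 (76452989 to 76477277), a ribosome biogenesis gene on the minus strand, and no exons of the pair overlap. Bop1 differed by 0.15 ± 0.13 log2 units at day 7 (adjusted p = 0.883, limma) and by 0.07 ± 0.13 at day 14 (adjusted p = 0.848).

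**Figure D1:**
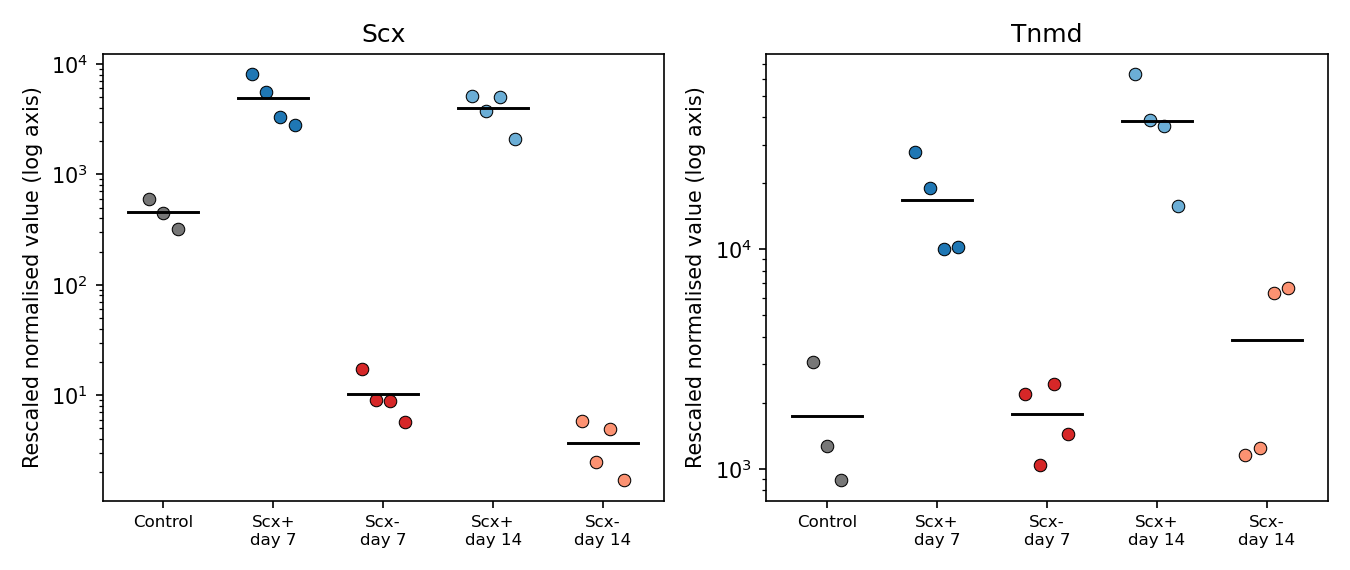
Rescaled signal of Scx and Tnmd in each of the 19 libraries, on a log axis, by group, with the group mean as a bar. Scx lay between 1.7 and 17.2 in the Scx- libraries and between 2095.7 and 8044.2 in the stimulated Scx+ libraries.

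The comparison of Scx- with Scx+ at day 7 asked how the genotypes differed early in the response of the tendon to the stimulus. Without an unstimulated Scx- group, a difference present beforehand cannot be told from a changed response. Tendon genes were lower: Tnmd, which encodes the tendon membrane glycoprotein tenomodulin, averaged 1779 ± 650 in Scx- against 16761 ± 8441 in Scx+ (SD, n = 4 each), a log2 fold change of -3.18 ± 0.62 (SE; adjusted p = 0.0198). Fibromodulin (Fmod), a proteoglycan of collagen fibrils, fell by 2.70 ± 0.55 (adjusted p = 0.0244) and chondroadherin (Chad), a matrix protein of cartilage and tendon, by 3.98 ± 0.86 (adjusted p = 0.0435). Interferon-induced genes were higher: Irf7, a transcription factor of the interferon system, rose by 2.35 ± 0.27 (adjusted p = 0.000442), Ifit3 by 2.94 ± 0.42 and Ifit1 by 2.88 ± 0.49. Plac9a, which encodes a small secreted protein, rose by 2.52 ± 0.25 (adjusted p = 9.94e-05), with all 4 Scx- libraries above all 4 Scx+ libraries.

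By list, 14 of 23 interferon response genes were higher and none lower (22 adjusted over the list alone; median 1.71; camera adjusted p = 1.52e-41, and adjusted p = 0.0200 with an estimated correlation). Of 14 tendon lineage genes, 3 were lower (8 adjusted over the list alone; median -1.55; camera adjusted p = 7.06e-11, but adjusted p = 0.0814 with an estimated correlation). The mean log2 value of the tendon list was 10.78 ± 0.84 against 12.71 ± 0.26 and that of the interferon list 11.49 ± 0.72 against 9.67 ± 0.50, each without overlap (SD, n = 4 each; exact permutation p = 0.0286). The main fibrillar collagens did not pass: Col1a1 differed by -0.65 ± 0.41 (adjusted p = 0.80), Col1a2 by -0.61 ± 0.42 and Col3a1 by -0.26 ± 0.41, and the transcription factor gene Mkx by -0.79 ± 0.41 (adjusted p = 0.767). All 11 genes of the fibrillar collagen list were negative, with 0 passed (1 lower adjusted over the list alone; median -0.60; camera adjusted p = 0.000909, but adjusted p = 0.404 with an estimated correlation). The mean log2 value of this list was 14.35 ± 0.49 in Scx- and 15.44 ± 0.43 in Scx+, without overlap (SD, n = 4 each, exact permutation p = 0.0286). Among 18 macrophage and monocyte genes only the Fc receptor gene Fcgr1 passed over all genes, higher by 1.36 ± 0.30 (median of the list 0.52, camera adjusted p = 4.84e-06, but adjusted p = 0.404 with an estimated correlation). The mean log2 value of that list was 12.50 ± 0.56 in Scx- and 11.87 ± 0.12 in Scx+, without overlap (SD, n = 4 each, exact permutation p = 0.0286). None of 22 skeletal muscle fibre genes passed (median 2.16; camera adjusted p = 9.69e-08, but adjusted p = 0.411 with an estimated correlation). They took 3.34 ± 2.58% of the signal in Scx- and 1.19 ± 1.21% in Scx+ (SD, n = 4 each), against 28.3 ± 2.83% in the controls (n = 3). None of 38 cell cycle genes passed (median -0.16; camera adjusted p = 0.203). The muscle median was 1.0 without Scx+ replicate 2, the macrophage median 0.23 without Scx- replicate 4 and the fibrillar collagen median -0.37 without Scx- replicate 2. With the muscle list as a covariate the fibrillar collagen median was -0.16, with 8 of 11 genes negative. The tendon median was then -1.48, with 12 of 14 negative.

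Erythroid genes were lower at day 7 in Scx-, 6 of 8 of them (8 adjusted over the list alone; camera adjusted p = 1.50e-24, and adjusted p = 0.00556 with an estimated correlation). Alas2, which encodes the first enzyme of haem synthesis in red cell precursors, averaged 86.8 ± 103 in Scx- and 9575 ± 6856 in Scx+ (SD, n = 4 each), with 285 ± 26.2 in the controls. It fell by 7.32 ± 0.88 log2 units in Scx- (adjusted p = 0.000819). The globin gene Hbb-bs was listed at 0 in the 4 Scx- and the 3 control libraries and at 28482.1, 77618.2, 29172.4 and 18305.9 in Scx+. These zeros do not mean that globin signal was absent. The entry Hbb-b1 stood at 13996.8, 11722.8 and 19805.8 in the controls and at 1657.9, 128.8, 6014.9 and 601.5 in Scx-. In Scx+ it stood at 143400, 581934, 257644 and 122816. Erythroid genes took 1.21 ± 0.852% of the signal in Scx+ at day 7, 0.00868 ± 0.0111% in Scx- (n = 4 each) and 0.0306 ± 0.00458% in the controls (n = 3). Endothelial cell genes were also on the lower side, with 14 of 14 negative and 0 passed (0 adjusted over the list alone; median -0.53; camera adjusted p = 8.20e-06, but adjusted p = 0.404 with an estimated correlation), and a median of -0.35 without Scx- replicate 4.

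In all, 128 of 16625 genes passed at day 7, 72 higher and 56 lower, and the authors' table has 755 genes under an adjusted p of 0.05. That table has Col1a1 at -0.73 ± 0.22 (SE; adjusted p = 0.0221) and Tnmd at -3.23 ± 0.38 (adjusted p = 1.14e-14). It has Fmod at -2.48 ± 0.65 (adjusted p = 0.00646) and Mkx at -0.82 ± 0.34 (adjusted p = 0.171). By camera, 20 of 34 lists passed, but 2 (interferon response and erythroid) with an estimated correlation. The gene count was 48, 46 and 74 without Scx+ replicates 1, 2 and 3, 46 and 73 without Scx- replicates 2 and 3, 53 with the muscle list as a covariate and 478 with sample quality weights. Without any one of Scx+ replicates 1 to 3 or Scx- replicates 2 to 4, Fmod and Chad no longer passed (adjusted p = 0.0576 to 0.174). The call of Tnmd ended without Scx+ replicate 1 or 2 or Scx- replicate 2 or 4 (0.0653 to 0.0927), and that of Fcgr1 without any library but Scx- replicate 1 (0.0502 to 0.195). With the muscle covariate Fmod, Chad and Fcgr1 had an adjusted p of 0.0900, 0.0929 and 0.123, at log2 fold changes of -2.30, -3.25 and 1.30. Tnmd, Irf7 and Plac9a still passed there by limma, at -2.59, 2.05 and 2.72 (adjusted p = 0.0490, 0.000345 and 2.56e-05). In a fit of these 2 groups alone, Ifit3, Ifit1, Fmod and Fcgr1 had an adjusted p of 0.0748, 0.0875, 0.0653 and 0.0794.

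At day 14, the same comparison asked which differences were present later in the response. Tnmd averaged 3847 ± 3062 in Scx- against 38502 ± 19282 in Scx+ (SD, n = 4 each), a log2 fold change of -3.63 ± 0.62 (SE; adjusted p = 0.0130). Plod1, which encodes a lysyl hydroxylase that prepares collagen for crosslinking, fell by 0.95 ± 0.15 (adjusted p = 0.00680), and Cybrd1, which encodes a ferric reductase, by 3.68 ± 0.56 (adjusted p = 0.00597). Cthrc1, which encodes a secreted protein of remodelling tissue, fell by 1.95 ± 0.39 (adjusted p = 0.0312), and Thbs4, a thrombospondin gene of tendon matrix, by 1.94 ± 0.40 (adjusted p = 0.0378). Plac9a rose by 2.66 ± 0.25 (adjusted p = 4.43e-05), Plac9b by 2.26 ± 0.36, Tmem254b by 1.60 ± 0.21 and Esr1, which encodes estrogen receptor alpha, by 1.12 ± 0.21 (adjusted p = 0.0214).

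Matrix lists lay lower at day 14 in Scx-. Of 24 collagen processing and crosslinking genes, 2 were lower (12 adjusted over the list alone; median -0.69; camera adjusted p = 3.85e-11). So were 2 of 31 matricellular and elastic matrix genes (9 adjusted over the list alone; median -0.58; camera adjusted p = 2.42e-06) and 2 of 14 tendon lineage genes (6 adjusted over the list alone; median -1.16; camera adjusted p = 2.23e-05). None of 11 fibrillar collagen genes passed (6 lower adjusted over the list alone; median -0.95; camera adjusted p = 0.00172). With an estimated correlation these 4 lists did not pass (adjusted p = 0.592 each with an estimated correlation). Col1a1 differed by -1.08 ± 0.41 (adjusted p = 0.273), Col1a2 by -1.01 ± 0.42, Col3a1 by -0.67 ± 0.41, Fmod by -2.28 ± 0.55 (adjusted p = 0.0897) and Mkx by -1.16 ± 0.41 (adjusted p = 0.245). The mean log2 value of the fibrillar collagen list was 14.14 ± 0.78 in Scx- and 15.04 ± 0.30 in Scx+ (SD, n = 4 each; exact permutation p = 0.0286). That of the tendon list was 11.62 ± 0.93 and 13.02 ± 0.49, with overlap (SD, n = 4 each, exact permutation p = 0.0571). None of 23 interferon response genes passed (median -0.55; camera adjusted p = 0.000204, but adjusted p = 0.722 with an estimated correlation). The mean log2 value of this list was 8.43 ± 0.33 in Scx- and 8.96 ± 0.38 in Scx+, without overlap (SD, n = 4 each, exact permutation p = 0.0286). Of its genes, 23 were negative with the muscle covariate and 21 without Scx- replicates 1 and 2. Skeletal muscle fibre genes had a median of 1.95 with none of 22 passed (camera adjusted p = 3.01e-05, but adjusted p = 0.722 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of 0.62 with none of 33 passed (camera adjusted p = 3.35e-12, but adjusted p = 0.592 with an estimated correlation). Without Scx- replicate 2 the medians were -0.46 for fibrillar collagens, -0.31 for matricellular genes, -0.41 for collagen processing, -0.35 for the interferon response and 0.35 for oxidative phosphorylation. Without Scx+ replicate 1 the muscle median was 0.94.

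Markers of other tissue lay on the higher side where these matrix lists lay lower, with none of the muscle or adipocyte genes passed. All 11 adipocyte genes were positive (0 adjusted over the list alone; median 1.54; camera adjusted p = 0.00984, but adjusted p = 0.722 with an estimated correlation). The adipocyte call also ended without Scx+ replicate 2, Scx- replicate 1 or Scx- replicate 3 (adjusted p up to 0.0919). Muscle transcripts took 17.1%, 19.8%, 4.76% and 4.56% of the signal in Scx- replicates 1 to 4, where fibrillar collagens took 3.34%, 1.90%, 12.7% and 8.24%. In Scx+ at day 14 muscle transcripts took 4.41 ± 3.82% and fibrillar collagens 10.5 ± 2.18% (SD, n = 4). The 5 matrix lists tested together were fibrillar collagens, other collagens, collagen processing and crosslinking, matricellular and elastic matrix, and proteoglycans. Without Scx- replicates 1 and 2, their members (110 genes) had a median of -0.11, against -0.65 with all libraries. The tendon lineage list, not among them, went from -1.16 to -0.66 without these libraries, with 11 of 14 genes negative and 0 passed. Plac9a, Plac9b and Tmem254b still passed without this pair (adjusted p = 8.36e-05, 0.00205 and 0.000339). Tnmd, Plod1, Cybrd1, Esr1, Cthrc1 and Thbs4 did not pass without the pair (adjusted p = 0.198, 0.121, 0.0909, 0.0909, 0.493 and 0.368). Their log2 fold changes there were -2.41, -0.72, -2.76, 1.27, -1.35 and -1.72, so the lost calls do not by themselves show that the pair was their source.

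**Figure D2:**
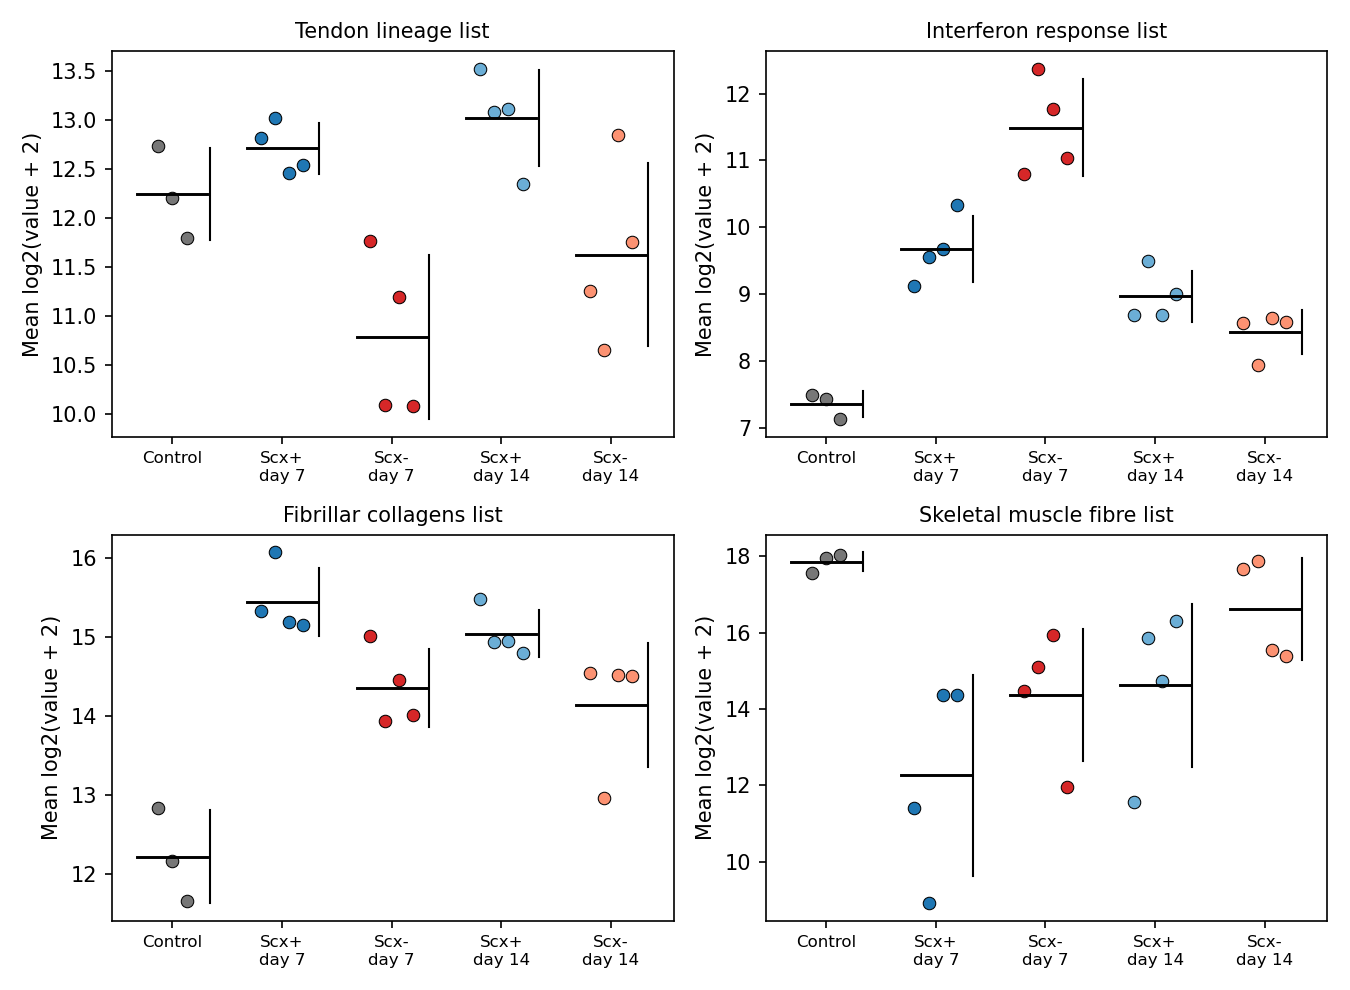
Mean log2 of the rescaled signal plus 2 of the tendon lineage, interferon response, fibrillar collagen and skeletal muscle fibre lists in each of the 19 libraries, by group; horizontal lines are group means and vertical lines 1 SD to either side. At day 7 the interferon list averaged 11.49 in Scx- and 9.67 in Scx+, and the tendon list 10.78 and 12.71.

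In all, 86 genes passed at day 14, 18 higher and 68 lower, and the authors' table has 177. That table has Tnmd at -3.34 ± 0.60 (SE; adjusted p = 1.72e-05) and Fmod at -1.89 ± 0.50 (adjusted p = 0.0237). It has Col1a1 at -0.88 ± 0.47 (adjusted p = 0.443) and Mkx at -1.19 ± 0.44 (adjusted p = 0.230). By camera 13 of 34 lists passed, and 0 with an estimated correlation or by fry, where 2429 genes had an unadjusted p under 0.05 in limma. The count of genes was 8 without the muscle-rich pair, 31 with the muscle covariate, 48 with sample quality weights and 9 in a fit of these 2 groups alone, in which of the genes named above Plac9a and Scx passed (adjusted p = 0.0207 and 1.09e-05). It was 22, 40 and 49 without Scx+ replicates 1, 2 and 3, and 44, 36 and 200 without Scx- replicates 1, 2 and 3. Tnmd and Esr1 no longer passed without Scx+ replicate 1 or Scx- replicate 2 (adjusted p = 0.0578 to 0.105). Cthrc1 did not pass without any one of Scx+ replicates 1 to 3 or Scx- replicates 1 and 2, and Thbs4 without any library but Scx- replicate 3 (adjusted p = 0.0654 to 0.167). On the deposited scale, which shifted the median of all genes by -0.23, 993 genes passed, 37 higher and 956 lower (3.73% higher, against 20.9% after rescaling); library totals shifted it by -0.13.

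The genotype effects at the 2 days were compared with each other to ask what changed between them. The interferon genes Irf7 and Ifit3 differed. The effect of genotype at day 14 less that at day 7 was -2.56 ± 0.38 log2 units for Irf7 (SE, n = 4 in each of 4 groups; adjusted p = 0.0238) and for Ifit3 -3.69 ± 0.60 (adjusted p = 0.0496). All 23 interferon response genes passed adjusted over the list alone, and 2 over all genes (median -2.25; camera adjusted p = 4.70e-53, and adjusted p = 0.0142 with an estimated correlation). Bpgm, which encodes the enzyme of red cells that makes bisphosphoglycerate, moved the other way, by 3.07 ± 0.44 (adjusted p = 0.0238). So did 7 of 8 erythroid genes adjusted over the list alone (camera adjusted p = 5.59e-13, and adjusted p = 0.0422 with an estimated correlation). For Tnmd the effects at the 2 days differed by -0.45 ± 0.87, for Scx by -0.82 ± 0.55 and for Col1a1 by -0.42 ± 0.58, with an adjusted p of 1.0 each.

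Of all genes, these 3 passed, and 721 had an unadjusted p under 0.05. None passed without Scx+ day 7 replicate 3, Scx- day 7 replicate 2, Scx+ day 14 replicate 1 or 2, or Scx- day 14 replicate 3 or 4. A single gene passed without Scx+ day 7 replicate 1 or 2, Scx- day 7 replicate 3 or Scx+ day 14 replicate 3, and 37 passed without Scx- day 7 replicate 1. The call of Bpgm ended without Scx+ day 7 replicate 3, Scx- day 7 replicate 2, any one of Scx+ day 14 replicates 1 to 3, or Scx- day 14 replicate 3 or 4 (adjusted p = 0.0508 to 0.0890). That of Irf7 ended without any one of Scx+ day 7 replicates 1 to 3, Scx- day 7 replicates 2 and 3, Scx+ day 14 replicates 1, 2 and 4, or Scx- day 14 replicates 3 and 4 (0.0508 to 0.0945). That of Ifit3 ended without any library but Scx+ day 7 replicate 4, Scx- day 7 replicates 1 and 4 and Scx+ day 14 replicate 4 (0.0577 to 0.180). In a fit of the 4 stimulated groups alone limma called 0 genes, with Bpgm and Irf7 at an adjusted p of 0.0853 each and Ifit3 at 0.155. By camera 13 of 34 lists passed, but 2 with an estimated correlation and 2 by fry; by camera 20 passed without Scx- day 14 replicate 2. The median of all genes shifted by -0.15 on the deposited scale and by -0.15 with library totals.

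A set of 30 genes passed in the same direction at both days, and 0 in opposite directions. Of the 128 genes passed at day 7, 82 had the same sign at day 14, and of the 86 passed at day 14, 84 had the same sign at day 7. There were 8 higher genes where 0.0780 was the product of the 2 counts over the genes tested, and 22 lower where it was 0.229. Beside Scx, Tnmd, Plac9a, Plac9b, Tmem254b, Cybrd1 and Esr1 they include Lrmda (3.29 and 4.28 log2 units higher at days 7 and 14) and Gt(ROSA)26Sor, the noncoding gene of a locus used for transgenes (-1.09 and -1.45), both chosen after their values were seen. In 22 of the 30 genes the Scx- groups lay nearer to the controls than the Scx+ groups did. Plac9a averaged 5856 ± 1496 in the controls (SD, n = 3), 3264 ± 769 and 5661 ± 1762 in Scx- at days 7 and 14, and 563 ± 105 and 899 ± 327 in Scx+ (SD, n = 4 each). Plac9a, Plac9b, Tmem254b and Lrmda lie within 5 Mb of each other on chromosome 14. Fold changes at the 2 days correlated across the 16625 genes with Pearson r = 0.467 and Spearman rho = 0.422 (covariance 0.207), and genes are not independent replicates. The comparisons share no library, but both use the same variance estimate of each gene from 1 fit. Calls at the 2 days are therefore not independent, and the products given above are only a rough reference. The correlation was 0.208 without the muscle-rich pair and 0.247 with the muscle covariate, where 7 and 12 genes passed at both days. The shared count was 11, 11, 12 and 15 without Scx+ day 7 replicate 1, Scx+ day 7 replicate 2, Scx- day 7 replicate 2 and Scx+ day 14 replicate 1.

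**Figure D3:**
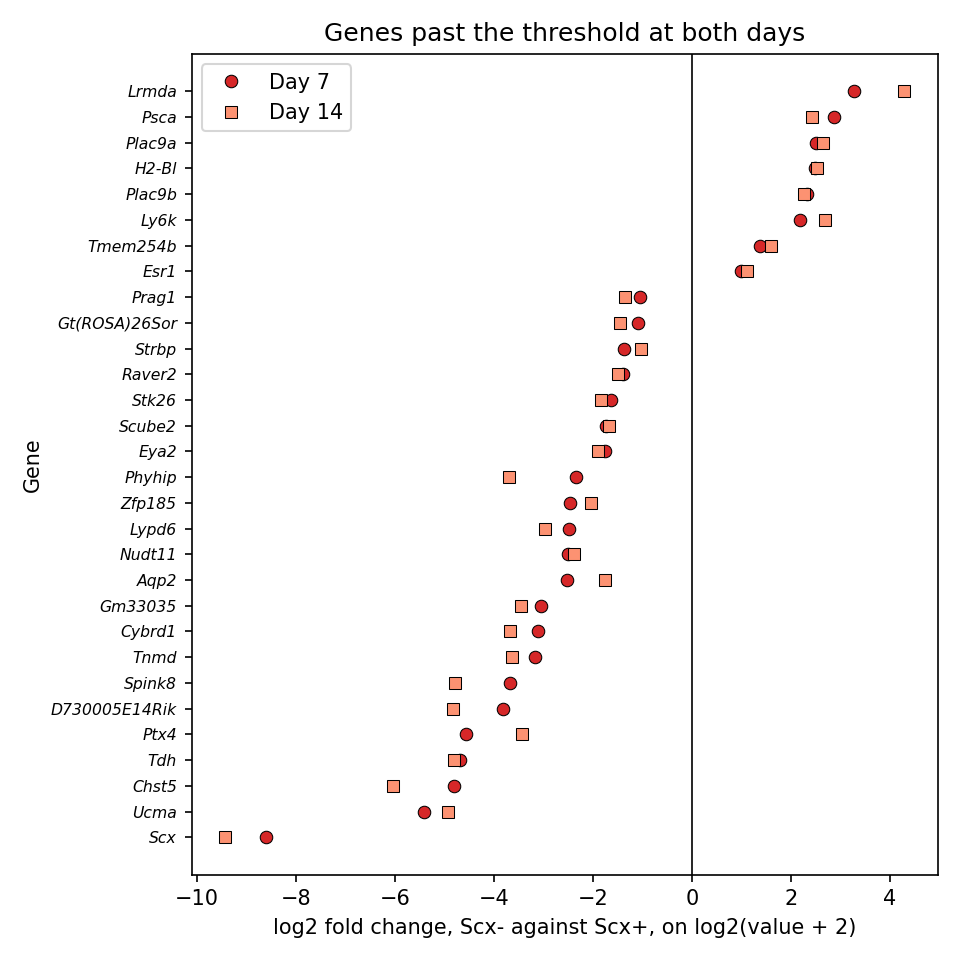
Log2 fold change of Scx- against Scx+ at day 7 and at day 14 for each of the 30 genes that passed at both days. Of these genes 8 were higher and 22 lower, and Scx lay lowest, at -8.61 and -9.43.

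The response of Scx+ mice to the stimulus was measured against the unstimulated controls, which had no tamoxifen. Matrix genes rose steeply by day 7 (n = 4 against 3): periostin (Postn), a matricellular protein gene, by 7.41 ± 0.35 log2 units (SE; adjusted p = 2.47e-10) and Cthrc1 by 8.23 ± 0.43. Fibrillin 2 (Fbn2), an elastic fibre gene, rose by 8.54 ± 0.48, and the collagenase gene Mmp13 by 8.11 ± 0.98. Col1a1 rose by 4.30 ± 0.45, Col3a1 by 3.90 ± 0.45, Scx by 3.36 ± 0.42, Tnmd by 3.33 ± 0.67 and Mkx by 2.36 ± 0.45 (adjusted p at most 0.000448). Fmod differed by 0.78 ± 0.60 (adjusted p = 0.268). At day 14 (n = 4 against 3) the values were 7.15 ± 0.35 for Postn, 8.58 ± 0.43 for Cthrc1, 4.03 ± 0.45 for Col1a1, 3.10 ± 0.42 for Scx and 4.51 ± 0.67 for Tnmd (adjusted p = 4.52e-05). Fmod differed by 1.22 ± 0.60 (adjusted p = 0.0919).

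Of 38 cell cycle genes 34 were higher at day 7, among them Aurkb, a mitotic kinase gene, by 7.66 ± 0.58, and 32 at day 14 (35 and 32 adjusted over the list alone; medians 4.15 and 2.50). Matricellular and elastic matrix genes were higher for 24 of 31 at both days with 1 lower at day 7 (24 and 24 higher adjusted over the list alone; medians 2.51 and 2.57). Fibrillar collagens were higher for 9 and 8 of 11 with 1 lower (9 and 8 adjusted over the list alone). Interferon response genes were higher for 21 and 19 of 23 (22 and 19 adjusted over the list alone), and macrophage and monocyte genes for 16 and 13 of 18 (16 and 13 adjusted over the list alone). All 33 nuclear genes of oxidative phosphorylation were lower at both days (33 and 33 adjusted over the list alone; medians -2.23 and -1.99), with cytochrome c (Cycs) down by -2.34 ± 0.26 at day 7. Of 22 muscle fibre genes 19 were lower at day 7 and 15 at day 14, with 1 higher (19 and 17 lower adjusted over the list alone). Myh4, the myosin gene of fast fibres, fell by 8.05 ± 1.30 and 7.82 ± 1.30. Muscle transcripts took 28.3 ± 2.83% of the control signal (SD, n = 3), against 1.19 ± 1.21% and 4.41 ± 3.82% in Scx+ (SD, n = 4 each). All genes, those of matrix and tendon among them, were thus compared across tissue of unequal muscle content. The rises given above may in part reflect this, and the part due to the stimulus was not separated. By camera 17 of 34 lists passed at each day, and 0 with an estimated correlation. For the lists named here the adjusted p was 0.468 to 0.489 at day 7 and 0.489 to 0.651 at day 14, each with an estimated correlation.

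In all, 10192 genes passed at day 7 (5617 higher and 4575 lower) and 9293 at day 14 (5143 and 4150), against 9820 and 7987 in the authors' table. With library totals the median of all genes shifted by 0.65 and 0.58, and the counts became 11420 (78.6% higher, against 55.1%) and 10537 (79.9%, against 55.3%). With the muscle covariate 5115 genes passed at day 7. The fold changes of the 2 days correlated across genes with r = 0.95 (covariance 3.07). Simulated unchanged groups set against shared simulated controls gave r = 0.570 (covariance 0.155). The observed covariance was higher by 2.91, so simulated noise of shared controls made up a small part of it. Differences of the controls beyond such noise, tamoxifen among them, are still shared by both days and cannot be split off. At both days 4671 genes were higher (1738 as the product of the 2 counts over the genes tested) and 3833 lower (1142), with part of this excess also open to the shared controls.

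Scx- mice were set against the same Scx+ controls, so genotype, stimulus and tamoxifen all differ and cannot be parted here. Most matricellular and elastic matrix genes and Mkx were higher than in the controls, while Tnmd did not pass at either day. At day 7 (n = 4 against 3) Postn rose by 7.25 ± 0.35 log2 units (SE; adjusted p = 2.72e-10), Col1a1 by 3.65 ± 0.45, Col3a1 by 3.64 ± 0.45 and Mkx by 1.58 ± 0.45. Tnmd differed by 0.16 ± 0.67 (adjusted p = 0.853). Fmod fell by 1.92 ± 0.60 (adjusted p = 0.0112, but 0.0831 without control replicate 1), Chad by 7.10 ± 0.93 and Scx by 5.25 ± 0.42. Irf7 rose by 5.21 ± 0.29 and Oas3, another interferon-induced gene, by 8.46 ± 0.58. At day 14 Postn rose by 6.15 ± 0.35, Col1a1 by 2.95 ± 0.45, Col3a1 by 3.36 ± 0.45 and Mkx by 1.66 ± 0.45, while Chad fell by 4.84 ± 0.93 and Scx by 6.33 ± 0.42. Tnmd differed by 0.88 ± 0.67 (adjusted p = 0.296) and Fmod by -1.06 ± 0.60 (adjusted p = 0.158).

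All 23 interferon response genes were higher at day 7 in Scx- and 10 at day 14 (23 and 10 adjusted over the list alone; medians 4.17 and 0.97; adjusted p = 0.399 and 0.720 with an estimated correlation). Cell cycle genes were higher for 34 and 31 of 38 (34 and 32 adjusted over the list alone; adjusted p = 0.466 and 0.558 with an estimated correlation). Matricellular and elastic matrix genes were higher for 24 and 23 of 31 (24 and 23 adjusted over the list alone; adjusted p = 0.429 and 0.558 with an estimated correlation). Of 14 tendon lineage genes 4 were higher and 6 lower at day 7, and 4 higher and 5 lower at day 14 (4 and 4 higher, 6 and 5 lower adjusted over the list alone; camera adjusted p = 0.241 and 0.567). In Scx+ 6 were higher and 3 lower at day 7, and 5 and 2 at day 14 (6 and 6 higher, 3 and 3 lower adjusted over the list alone; camera adjusted p = 0.574 and 0.367). Muscle fibre genes, with a share of 3.34 ± 2.58% at day 7 and 11.6 ± 8.05% at day 14 (SD, n = 4 each), were lower for 14 and 2 of 22 (16 and 1 adjusted over the list alone). In all, 9677 genes passed at day 7 (5373 higher) and 7291 at day 14 (4244 higher), against 9110 and 5101 in the authors' table. With library totals the median of all genes shifted by 0.67 and 0.45, and 10933 (81.9% higher, against 55.5%) and 8568 genes (84.1%, against 58.2%) passed. On the deposited scale the day 14 median shifted by -0.33, with 7911 genes (35.2% higher), and in a fit of the 2 groups alone 4237 passed.

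To ask whether genes of the growth response differed by genotype, genes called in Scx+ against control at 1 day were tested in the genotype comparison of the other day. The 5617 genes higher at day 7 had a median of -0.22 in Scx- against Scx+ at day 14 (camera p = 4.34e-25; p = 0.0159 with an estimated correlation). The 4575 lower genes had a median of 0.33 (camera p = 2.90e-35; p = 0.0288 with an estimated correlation). Without the muscle-rich pair the medians were -0.01 and 0.02 (camera at the preset correlation, p = 0.398 and 0.720). The 5143 genes higher at day 14 had a median of -0.08 in the genotype comparison at day 7 (camera p = 9.70e-05, but p = 0.342 with an estimated correlation). The 4150 lower genes had a median of 0.15 (camera p = 7.45e-09, but p = 0.285 with an estimated correlation). With the muscle covariate these medians turned to 0.04 and -0.02. Without Scx- day 14 replicate 2 the medians tested at day 14 were -0.14 and 0.20, and that of the genes higher at day 14 was -0.05 and -0.14 without Scx- day 7 replicates 3 and 4.

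Between day 7 and day 14, interferon and immune cell genes fell in Scx- mice. Irf7 fell by 3.63 ± 0.27 log2 units (SE, n = 4 against 4; adjusted p = 1.62e-06) and Oas3, an antiviral sensor gene, by 4.74 ± 0.53. Mx1, an antiviral GTPase gene, fell by 5.31 ± 0.73 and the chemokine gene Cxcl10 by 5.84 ± 0.84. All 23 interferon response genes were lower (23 adjusted over the list alone; median -2.89; camera adjusted p = 3.27e-40, and adjusted p = 0.0455 with an estimated correlation). Of 18 macrophage and monocyte genes 12 were lower (17 adjusted over the list alone; median -1.38; camera adjusted p = 7.80e-15, but adjusted p = 0.192 with an estimated correlation). Fcgr1 fell by 2.48 ± 0.30 and Ly6c2, a monocyte surface gene, by 3.58 ± 0.60. Of 38 cell cycle genes 5 were lower, among them the replication gene Mcm3 by -0.94 ± 0.19 (17 adjusted over the list alone; camera adjusted p = 3.27e-12, but adjusted p = 0.716 with an estimated correlation). Muscle fibre genes lay on the higher side, with 22 of 22 positive and 0 passed (0 adjusted over the list alone; median 2.09, and 1.28 without Scx- day 7 replicate 4; camera adjusted p = 4.26e-05, but adjusted p = 0.716 with an estimated correlation). Their share of the signal was 3.34 ± 2.58% at day 7 and 11.6 ± 8.05% at day 14 (SD, n = 4 each). Nuclear genes of oxidative phosphorylation were positive for 33 of 33 with 0 passed (0 adjusted over the list alone; median 0.50, and 0.27 without Scx- day 14 replicate 2; camera adjusted p = 9.22e-08, but adjusted p = 0.716 with an estimated correlation). Tnmd differed by 0.73 ± 0.62 (adjusted p = 0.518) and Col1a1 by -0.69 ± 0.41 (adjusted p = 0.338).

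In all, 873 genes passed in Scx- between the days, 232 higher and 641 lower, against 1443 in the authors' table. The count was 281 without the muscle-rich pair, where Mcm3 did not pass (adjusted p = 0.0576), 515 with the muscle covariate and 317 in a fit of the 2 groups alone. It was 370 and 380 without Scx- day 7 replicates 2 and 4, and 427, 555 and 1481 without Scx- day 14 replicates 1, 2 and 4. With library totals the median of all genes shifted by -0.22 and 1349 genes passed (8.45% higher, against 26.6%), and on the deposited scale by -0.25 with 2604 genes (4.30% higher).

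In Scx+ mice 5 genes passed between the days, but 616 did with sample quality weights. Scara5, which encodes a scavenger receptor, rose by 2.98 ± 0.42 log2 units. Bpgm, the lamin gene Lmnb1 and the receptor kinase gene Grk3 fell by 2.07 ± 0.31, 1.55 ± 0.23 and 1.49 ± 0.22 (SE, n = 4 against 4; adjusted p = 0.0156 each). The predicted gene Gm15674, named after its value was seen, was also higher, by 1.33 ± 0.21 (adjusted p = 0.0218). Of 38 cell cycle genes 0 passed over all genes and 34 were lower adjusted over the list alone (median -1.48; camera adjusted p = 5.69e-25, but adjusted p = 0.331 with an estimated correlation). Without Scx+ day 14 replicate 4 this median was -0.78. The interferon response list had a median of -0.59 with none of 23 passed (8 lower adjusted over the list alone; adjusted p = 0.499 with an estimated correlation), and of -0.25 without Scx+ day 7 replicate 4. Irf7 differed by -1.07 ± 0.27 (adjusted p = 0.170). Muscle fibre genes were positive for 22 of 22 with 0 passed (0 adjusted over the list alone; median 2.44, and 1.29 without Scx+ day 7 replicate 2; camera adjusted p = 1.43e-08, but adjusted p = 0.499 with an estimated correlation). Erythroid genes were negative for 8 of 8 with 0 passed (6 lower adjusted over the list alone; camera adjusted p = 7.73e-07, but adjusted p = 0.331 with an estimated correlation), and took 1.21 ± 0.852% of the signal at day 7 and 0.0986 ± 0.0529% at day 14 (SD, n = 4 each). Tnmd differed by 1.17 ± 0.62 (adjusted p = 0.534) and Col1a1 by -0.27 ± 0.41 (adjusted p = 0.872).

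These 5 genes compare with 1757 at an unadjusted p under 0.05 in limma and 796 in the authors' table. The count was 0 without Scx+ day 7 replicate 3, 1 without Scx+ day 7 replicate 2 or Scx+ day 14 replicate 3, and 2 without Scx+ day 7 replicate 4. It was 3 without Scx+ day 14 replicate 2, and 12 and 27 without Scx+ day 14 replicates 4 and 1. The calls of Scara5, Lmnb1 and Grk3 ended without any one of Scx+ day 7 replicates 2 to 4, those of Scara5 and Lmnb1 also without Scx+ day 14 replicate 3 (adjusted p = 0.0522 to 0.0926). That of Bpgm ended without Scx+ day 7 replicate 3 or Scx+ day 14 replicate 2 or 3 (adjusted p = 0.0731 to 0.0926). On the deposited scale, which shifted the median of all genes by -0.11, 28 genes passed (4 higher and 24 lower); with library totals 4 passed (1 higher and 3 lower), and with a trimmed mean 13 (8 higher and 5 lower).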

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

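Among 68 groups of 4 libraries tested for a library apart from the rest of its group, 2 list means in 1 library, Scx- day 14 replicate 2, met the criterion; chance flags about 1 in 20 groups, or 3.4 here. The mean log2 value of the fibrillar collagen list was 12.96 in that library, against 14.51 or more in the others of its group. That of the interferon response list was 7.93, against 8.57 or more. This library also had the highest share of muscle transcripts of its group, 19.8%.

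The effect of genotype differed between day 14 and day 7 by limma for Bpgm (3.07 log2 units), Ifit3 (-3.69) and Irf7 (-2.56). By camera it differed for 13 lists. The median differences were 1.20 for chondrocyte genes, 0.82 for endothelial cells, 1.46 for mast cells, 0.49 for osteoblasts and mineralisation, 0.29 for nuclear genes of oxidative phosphorylation and 0.91 for Schwann cells and nerve. They were -0.46 for collagen processing and crosslinking, -2.25 for the interferon response, -0.95 for lymphocytes, -0.77 for macrophages and monocytes, -0.50 for matricellular and elastic matrix and -1.18 for satellite cells and myoblasts. The erythroid median, 5.23, depends on the added value of 2, since several of these genes were listed at 0. Leaving out 1 library gave satellite medians of -2.30 to 0.0228, and the call ended without 9 of the 16 libraries: Scx+ day 7 replicates 1 and 2, Scx- day 7 replicates 1 to 3, Scx+ day 14 replicates 2 and 4, and Scx- day 14 replicates 3 and 4 (adjusted p up to 0.935). The osteoblast call ended without 7: Scx+ day 7 replicate 2, Scx- day 7 replicates 3 and 4, Scx+ day 14 replicates 1 and 4, and Scx- day 14 replicates 3 and 4 (up to 0.368). The Schwann cell call ended without 4: Scx+ day 7 replicate 2, Scx- day 7 replicate 3 and Scx- day 14 replicates 3 and 4 (up to 0.422). The mast cell call ended without Scx- day 7 replicate 3 (0.0633), and that of oxidative phosphorylation without Scx- day 14 replicate 2 (0.427). Other medians moved by more than 1.5 times with the call kept: chondrocyte genes without Scx+ day 7 replicate 2, Scx- day 7 replicate 4 or Scx- day 14 replicate 1 (lowest 0.63), collagen processing without Scx+ or Scx- day 14 replicate 1 (-0.30), and matricellular genes without Scx- day 14 replicate 2 (-0.24). Oxidative phosphorylation ranged from 0.0432 to 0.49, moved most by Scx- day 14 replicates 2 and 3 and also by Scx- day 7 replicate 1 and Scx+ day 14 replicate 1. With an estimated correlation only the interferon and erythroid lists passed, and the other 11 had an adjusted p of 0.234 to 0.827.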

How the results depend on the processing

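The deposited scale, the pseudocounts, the quality weights, the removal of the muscle-rich pair and an estimated correlation for genes of the other day's response were chosen after the data were seen. Leaving out 1 library at a time, the genes passed numbered 46 to 186 for genotype at day 7, 22 to 200 at day 14, 0 to 37 for the difference between the days, 9366 to 9986 and 8164 to 9222 for Scx+ against control at days 7 and 14, 8724 to 9381 and 5890 to 7992 for Scx-, 0 to 27 between the days in Scx+ and 370 to 1481 in Scx-. The lists passed numbered 17 to 22, 12 to 15, 9 to 20, 17 to 18, 14 to 18, 14 to 16, 14 to 18, 11 to 16 and 11 to 15 in the same order. At day 7 the gene count was 478 with quality weights and 53 with the muscle covariate. At day 14 it was 993 on the deposited scale, 48 with quality weights, 31 with the covariate, 8 without the muscle-rich pair and 9 with only the groups compared. The difference between the days gave 0 genes with quality weights, with the replicate block and with only these groups, and 721 at an unadjusted p under 0.05. Scx+ day 7 against control gave 5115 with the covariate and Scx- day 14 gave 4237 with only the groups compared. Between the days in Scx+, 13 passed with a trimmed mean, 28 on the deposited scale, 19 with no filter, 14 with a stricter filter, 17 with a pseudocount of 8, 616 with quality weights, 23 with the covariate and 13 with only the groups compared. In Scx- they were 1349 with library totals, 2604 on the deposited scale, 515 with the covariate, 281 without the pair and 317 with only the groups compared. No pairing of the samples by number was seen. Of 36 pairs with the same number 7 correlated over 0.1, with a median of -0.00146, against 0.0110 for the 108 other pairs. The other pairs ranged from -0.45 to 0.43, so a weak pairing could not have been seen. With the number as a block the gene counts were 120, 58, 0, 9665, 8585, 9074, 6513, 4 and 621 in the order above. Lists passed with an estimated correlation numbered 2 at day 7, 0 at day 14, 2 for the difference, 0 for each comparison with control, 0 between the days in Scx+ and 1 in Scx-. By fry they numbered 3, 0 and 2, then 27 for Scx+ day 7 against control, 1 between the days in Scx+ and 4 in Scx-. The covariate gave 13 lists at day 7, and the difference gave 21 without the pair. Genes of the day 14 response, tested for genotype at day 7, had medians of -0.0815 and 0.146 (limma, p = 0.342 and 0.285 with an estimated correlation) and, reversed, 0.0438 and -0.0167 with the covariate; those of day 7, tested at day 14, had -0.00695 and 0.0174 without the pair. Without 1 library these medians were -0.14 to -0.05, 0.10 to 0.19, -0.31 to -0.14 and 0.20 to 0.44. The genotype correlation between the days was 0.559 with a stricter filter, 0.514 with a pseudocount of 8, 0.359 with quality weights, 0.247 with the covariate, 0.208 without the pair and 0.361 to 0.529 without 1 library. Genes passed at both days numbered 12 with the covariate, 7 without the pair and 11 to 33 without 1 library. For the growth response the correlation was 0.962 with a stricter filter, 0.930 with the covariate and 0.929 to 0.954 without 1 library, with 4601 genes shared with the covariate and 7515 to 8430 without 1 library. The direction by camera also turned in the results that follow, given by their medians: 0.0583 for other collagens at day 14 without the pair and -0.0933 for muscle fibre genes with the covariate. For the difference between the days, they were -0.00396 for collagen processing (a median that kept its sign) and -0.20 for oxidative phosphorylation, each without the pair. Between the days in Scx+ they were 0.11 for immediate early genes without Scx+ day 7 replicate 4 (lowest -0.64, without replicate 3) and -0.12 for oxidative phosphorylation with the covariate. In Scx- they were -0.13 for matricellular genes without the pair (again with its sign kept) and -0.0644 for muscle fibre genes with the covariate. Medians that changed sign while the direction by camera did not were -0.0472 for lymphocyte genes at day 7 and 0.46 in the difference, each with a stricter filter, 0.00411 for proteoglycans at day 7 with the covariate, and 0.0228 for satellite cells in the difference without Scx+ day 7 replicate 2. In Scx+ day 7 against control, the covariate reversed Trp63 (0.34), Myf6 (0.61), Cdh15 (1.84) and Des (2.22). Scx was lower in all 24 alternative values run over both days. Of 138 list results with 3128 values, 382 values no longer passed, and of 806 named gene results with 16104 values, 852 no longer passed and 71 were stronger. The cause of these changes was not tested.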

Other observations

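The matrix list test and the test of gene positions were chosen only after the results they measure were seen, and the muscle-rich pair was picked from the data. Of the 35 splits of the libraries at day 7, only the real one (1 split) gave as many as 128 genes in Scx- against Scx+. The highest other gave 1 gene. This argues against chance but does not exclude it, since 1 of 35 is the smallest share possible and was not adjusted over the comparisons. At day 14, 4 of 35 splits gave at least 86 genes, and up to 1504, so chance cannot be excluded for the count; the large splits put Scx- replicates 1 and 2 with Scx+ replicate 4 and point to a structure of the samples that follows muscle transcripts. For the difference between the days 3 of 100 splits gave at least 3 genes, and up to 1717, which again points to structure. Only 4.34% of genes had an unadjusted p under 0.05 there, and 0 genes passed with quality weights, with the replicate block and with only these groups, so this count of 3 is not taken to exclude chance. For the comparisons with control (10192 and 9293 genes in Scx+, 9677 and 7291 in Scx-) only the real split of 35 gave as many, and the highest others were 6929, 7322, 6680 and 6560. Between the days the real splits gave 5 and 873 genes and the highest others 0 and 10 in Scx+ and Scx-. Each of these 6 counts stood first of its 35 splits. That argues against chance but, at 1 of 35 without adjustment, does not exclude it. The 5 genes in Scx+ also depended on single libraries.

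The 68 genes lower in Scx- at day 14 had a median of -1.95. The median was -1.77 (jackknife SD 0.231) with the muscle covariate and -1.69 (SD 0.180) without the muscle-rich pair, with all 68 genes negative in each fit. These genes were picked as lower in the same libraries, which favours falls that hold in such refits. The refits therefore cannot decide whether more muscle RNA was the cause. The calls of the 68 genes mostly ended (24 and 4 passed), and why was not tested. The medians moved by less than the SD of 0.283 with all libraries. Tnmd went from -3.63 ± 0.62 to -2.41 ± 0.58 and Cybrd1 from -3.68 ± 0.56 to -2.76 ± 0.56 without the pair (SE). The 5 matrix lists are another matter: their median went from -0.65 to -0.11 (SD 0.270) without the pair, so the lower matrix lists may come from these 2 libraries. With the muscle covariate it was -0.44 (SD 0.319), so muscle caught with the tendon is not shown to be the reason, and a weaker response of these samples also stays open. With the muscle covariate Tnmd, Plod1 and Cybrd1 still passed at day 14 by limma (-3.06, -0.84 and -3.18, adjusted p = 0.0174, 0.0174 and 0.0132). Cthrc1 and Thbs4 did not (-1.52 and -1.76, adjusted p = 0.0671 and 0.131). Lower Tnmd and Plod1 thus held at an equal muscle score, but neither passed without the pair. Whether they are an effect of Scx loss apart from muscle content stays open, and measurement in tendon freed of muscle could test it.

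For the 30 genes that passed at both days, the median change in the direction of the call was 2.55, and 2.48 (SD 0.194) with the muscle covariate. These genes were also picked from the same libraries, so this value cannot decide whether muscle RNA was the cause. A variant of strain or background linked to the modified alleles stays open: 7 of the genes lay within 5 Mb of another, against a median of 4 and at most 18 in 10000 random draws (permutation p = 0.194). Of these 7, Psca, Ly6k and D730005E14Rik lie beside Scx itself on chromosome 15, at 74.7, 74.8 and 79.9 Mb with Scx at 76.5 Mb, and Plac9a, Plac9b, Tmem254b and Lrmda lie on chromosome 14. Either group might reflect linked variation, the first most directly a variant linked to the modified Scx allele. Gt(ROSA)26Sor differed from the controls by -0.42 (SE 0.237) and -0.49 log2 units in Scx-, too close to the bound set to tell whether this locus was modified. The controls were also unstimulated, and every stimulated Scx+ library lay above them for this gene. Against Scx+ of the same day it differed by -1.09 and -1.45 at days 7 and 14, a comparison for which no bound was set. Genotyping of these regions or a second Scx allele could separate these.

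The interferon list was higher in Scx- at day 7, with a median of 1.71. With the macrophage list as a covariate it was 1.92 (SD 0.730), a spread too wide to exclude macrophage RNA. With the muscle list it was 1.42 (SD 0.409) with 0 of 23 genes negative, in a fit where oxidative phosphorylation went from 0.33 to 0.03. This argues against muscle RNA as the whole cause, although the bound set beforehand, a median above 1 by more than 2 SD, was not met. An infection, a cage effect or a difference in the timing of inflammation was not tested. Loss of Scx could heighten the interferon response at day 7 alone. At day 14 the list lay lower in Scx- than in Scx+ (median -0.55), though none of its genes passed. Its mean log2 values there were 8.43 and 8.96, without overlap (exact permutation p = 0.0286). At that day 10 of its 23 genes in Scx- and 19 in Scx+ were still above the controls. Single-cell profiles at several days could name the responding cells.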
